A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

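Total RNA of budding yeast, Saccharomyces cerevisiae, was measured on 8 arrays, of which 4 came from cultures with an empty vector and 4 from cultures with a plasmid for Kir2.1, an inwardly rectifying potassium channel of mammals. Per the labels' protocols, all strains grew at 26 °C in selective medium to the middle of exponential growth, RNA was taken with hot phenol and cleaned on a column, and biotin-labelled cRNA was made with a kit that primes from the 3' end of the transcript. The series describes its replicates as biological, at least 3 for each strain, and the labels number the arrays 1 to 4 in each group. The labels mark the 4 control arrays, and no Kir2.1 array, as a re-analysis. Any difference in handling or processing that goes with this mark cannot be told apart from the group difference. The groups differ in plasmid as well as in Kir2.1: the control carries pRSGPD426 and the other strain pRS416TEF-Kir2.1-HA. Kir2.1 itself was not analysed here, because the array was made for yeast genes.

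The deposited values are a standardized score for each probe set, since every array has a mean of 0 and a standard deviation of 1 over its 10715 probe sets. The lowest score on an array lies between -0.47 and -0.44 and the highest between 8.49 and 9.22, which is the shape of a linear intensity, not of a log value. How the authors summarized the probes, which background they removed and where the zero of the intensity scale lies are not given in the sources used here. The design fixed before the data were examined had assumed log2 values or values that a log2 could be taken of directly, so another treatment was needed. A log2 scale was rebuilt by placing the zero of each array 0.005 array standard deviations below its lowest score, taking log2 of the distance to that zero, and centring each array on the median of the tested genes. With this zero, the median standard deviation of vector control replicates 2 to 4 ran from 0.0975 in the dimmest decile of the probe sets to 0.0578 in the brightest. Zeros at 0.001 and 0.02 were tried as alternatives. Differences of dim genes depend on this zero more than those of bright genes. Before centring, the median gene lay 0.13 lower in the Kir2.1 arrays on the log2 scale (-0.13, Kir2.1 minus control), and the cause was not tested. All levels and differences are therefore relative to the median gene of the array. Leaving out the centring shifts every gene's difference by this amount and centring on the 75th percentile shifts every one by -0.04, so a sign that changes under them is not particular to 1 gene or list. Centring was chosen before any group difference was computed.

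The platform annotation gave 1 S. cerevisiae gene for 5498 probe sets, S. pombe genes for 1746 probe sets, several genes for 1 probe set, and no entry for 3470 probe sets. Symbols were updated through the gene identifiers of the RefSeq table of assembly R64, whose coordinates were not used because the deposited table names no build. For 47 genes with several probe sets, the brightest on average stood for the gene, which left 5449 genes. Of these, 118 were read from probe sets marked as shared between transcripts. No value column of the table was left unused. The number of arrays limits the precision: the median standard error of a log2 difference was 0.0912, and the median 95% interval reached 0.208 to either side. Between 84.9% and 88.6% of the tested genes lay above the 95th percentile of the S. pombe probe sets of their array.

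Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. The 31 gene lists tested were fixed before the data were examined, and 1 further list of plasmid-related genes was fixed to be read gene by gene. Lists were tested with limma's camera at the preset correlation of 0.01, adjusted over the 31 lists. Camera with an estimated correlation, the rotation test fry and an exact permutation test of the mean of each list per array stood beside it. With 4 arrays against 4, the exact two-sided p cannot go below 0.0286, and 18 of the 31 lists would have to reach that value for any to pass after adjustment, so this test could hardly pass a list. The standard error of a list mean was taken over arrays.

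The genes named in the text follow a rule fixed before the data were examined: the 15 largest rises and 15 largest falls among called genes whose groups do not overlap, up to 4 members of each list with the smallest p, all measured plasmid-related genes, and the transporters TRK1, TRK2, TOK1, ENA1 and PMA1. No gene qualified under the first part. Under the second part, 3 members are named for a list that passed and 1 for any other. Iron genes other than LSO1, the gene SSA4 and the genes that only the closing section names were chosen after their values were seen. A gene is said to lie within the background of an array where it is not above the 95th percentile of the S. pombe probe sets of that array.

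The fits were tested on simulated data for the comparison of 4 Kir2.1 and 4 control arrays over 5449 genes, of which 200 were changed. With independent noise of the size of each gene's own spread, 52.2% of genes changed by 0.5 on the log2 scale were recovered, 88.1% of those changed by 1 and 98.5% of those changed by 2, with 10 false calls. With changes added to the real arrays, the shares were 55.2%, 88.1% and 100%, with 7 other calls. A shift of 0.3 in 1 list was recovered and 0 of the 30 other lists were called. That list check used independent noise alone, with no correlation between genes. It therefore does not show how often lists whose genes move together are called falsely.

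Alternatives fixed in advance were quantile normalization, centring on the 75th percentile, filters on dim probe sets at the 95th and 99th percentile of the S. pombe probe sets on at least 4 arrays, all probe sets in the fit, the mean of the probe sets of a gene, shared probe sets left out, eBayes with a trend or robust, array weights, the replicate number as a block, each array left out in turn, an unmoderated test, and the plasmid-related genes left out of the lists. Alternatives chosen after seeing the data were no centring, the other zeros, scores with no log, principal components as covariates, sets of 2 and 3 arrays left out, and the exact permutation test of list means. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.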

Results

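Transcript levels were measured in yeast that expressed the mammalian potassium channel Kir2.1 from a plasmid and in yeast with an empty vector, on 4 arrays each. The comparison asks how the yeast transcriptome responds to a foreign ion channel, one of several membrane proteins the series set out to express under identical conditions. Levels are log2 values relative to the median gene of the same array, rebuilt from the authors' standardized scores, and differences are Kir2.1 minus vector control.

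Genes whose sequence yeast plasmids often carry were read first, because the labels give the groups different plasmids. URA3 (YEL021W), the selection marker of such plasmids and an enzyme of uracil synthesis, stood at 3.43 ± 0.31 (SD, n = 4) in the Kir2.1 arrays, with a difference of 0.09 and a standard error of 0.16 (limma adjusted p = 0.852), and a difference of -0.02 after quantile normalization. TDH3 (YGR192C), the glyceraldehyde-3-phosphate dehydrogenase gene whose promoter is known as GPD, differed by 0.19 (SE 0.05, adjusted p = 0.551). TEF2, a translation elongation factor gene read from a shared probe set, differed by 0.18 (SE 0.06, adjusted p = 0.551). After quantile normalization TDH3 and TEF2 each differed by 0.0077. CYC1 (YJR048W), the cytochrome c gene whose terminator such vectors hold, differed by -0.98 (SE 0.70, adjusted p = 0.711), and its values within the Kir2.1 group ranged from 0.61 to 3.43. None of the 4 measured genes passed over all genes, and 2 passed adjusted over the list alone. With array weights, 2 of them passed over all genes: CYC1 at a difference of -2.11 (adjusted p = 0.0192) and TDH3 at 0.16 (adjusted p = 0.0382). TEF1 and the genes of the native plasmid circle were not analysed here.

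No single yeast gene passed the threshold. Of 5449 genes, limma called 0 higher and 0 lower in the Kir2.1 arrays, the smallest adjusted p was 0.551, and 455 genes had an unadjusted p under 0.05, where 272 would be expected by chance. The unmoderated test also called 0 genes and gave 524 at an unadjusted p under 0.05. Of the 455 genes, 347 had a higher and 108 a lower mean in the Kir2.1 arrays. In 275 genes all 4 Kir2.1 values lay above all 4 control values and in 84 below them, together 6.59% of genes against 2.86% by chance. These counts depend on the scaling: quantile normalization left 271 genes at an unadjusted p under 0.05, no more than expected by chance, with 109 higher and 162 lower, centring on the 75th percentile gave 138 higher and 239 lower, and no centring 6 higher and 999 lower. The genes with separated values were then 87 above and 110 below, 139 and 191, and 10 and 661. Most measured differences were small, as 95% of genes differed by less than 0.30 on the log2 scale. The 95% interval of 5306 genes (97.4%) lay within 2-fold in either direction. Of the 5449 genes, 4768 lay above the background on at least 4 arrays. Changes of the remaining genes may be larger than shown, so their intervals do not exclude a 2-fold change. The count of 0 changed with array weights, which called 1017 genes higher and 718 lower and gave vector control replicate 1 a weight of 0.372 and Kir2.1 replicates 2 and 4 weights of 0.231 and 0.267. It also changed when vector control replicate 1 and Kir2.1 replicate 2 were left out together, a choice made from their values because each lay near arrays of the other group (326 higher, 182 lower).

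Among the gene lists, glycolysis, the cell wall, general stress and hexose transport and sensing were higher in the Kir2.1 arrays by the planned test. Ribosome biogenesis and heat shock proteins were lower. In all, 8 of 31 lists passed as higher and 3 as lower with the preset correlation. With an estimated correlation 0 lists passed (smallest adjusted p = 0.215) and fry passed 1 list. The same 8 arrays can be divided into 2 sets of 4 in 35 ways. With the preset correlation, 22 of these, the labelled one included, called as many lists. The estimated correlation passed 0 lists even in a division, described below, that called 1445 genes, so a miss under it decides little.

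All 16 measured genes of glycolysis and fermentation had a higher mean in the Kir2.1 arrays, with a list mean of 0.20 (SE 0.02), and the list mean on each Kir2.1 array lay above that on each control array. The list passed with camera at adjusted p = 1.11e-09 (adjusted p = 0.519 with an estimated correlation) and with fry at adjusted p = 0.0392, and its exact permutation p of 0.0286 is the smallest that 4 against 4 arrays can give. PGI1 (phosphoglucose isomerase) differed by 0.21 (SE 0.06), TDH3 by 0.19 (SE 0.05) and CDC19 (pyruvate kinase) by 0.19 (SE 0.06), and after quantile normalization by 0.08, 0.0077 and 0.01. No member passed over all genes and 11 passed adjusted over the list alone. These transcripts are among the brightest on the array. Relative to the median gene, bright genes as a class had a higher mean in the Kir2.1 arrays. The median difference was 0.12 in the brightest decile of genes, but also 0.06 in the dimmest, so it was not one of bright genes alone. With no centring, which shifts every difference by -0.13, the glycolysis mean was 0.07. After quantile normalization, which gives every array the same highest values, the list mean was 0.04 and the call was lost (adjusted p = 0.342).

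For cell wall integrity, 22 of 24 measured genes had a higher mean in the Kir2.1 arrays and the list mean was 0.19 (SE 0.09, adjusted p = 2.44e-07; adjusted p = 0.519 with an estimated correlation). BGL2, a glucanase of the wall, differed by 0.25 (SE 0.05), and the wall proteins SED1 and CCW14 differed by 0.23 each (SE 0.05 each). The list mean did not separate the groups: Kir2.1 replicate 2 stood at -0.11 from the 8-array mean, near the controls at -0.13 to -0.19, and vector control replicate 1 at 0.09. Adjusted over the list alone, 8 members passed. After quantile normalization the list mean was 0.12, and these 3 genes differed by 0.12, 0.07 and 0.10. Of the 66 named genes, 34 had a difference over 1.5 times smaller, or of the other sign, after quantile normalization.

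The general stress list, genes under the transcription factors Msn2 and Msn4, had a mean of 0.24 (SE 0.25) with 28 of 29 members higher, and passed at adjusted p = 0.00532 (adjusted p = 0.833 with an estimated correlation). HXK1, a hexokinase, differed by 0.28 (SE 0.12), TPS1, which makes trehalose phosphate, by 0.21 (SE 0.13) and HOR7 by 0.15 (SE 0.05), and after quantile normalization by 0.17, 0.11 and -0.02. The hexose transporter list also holds the sensor genes SNF3 and RGT2 and the regulator genes MTH1, STD1 and MIG1. It had a mean of 0.21 (SE 0.11) with 15 of 15 members higher, 11 of them above the background on at least 4 arrays (adjusted p = 0.00454, or adjusted p = 0.740 with an estimated correlation). HXT7, read from a shared probe set, differed by 0.24 (SE 0.09), HXT3 by 0.19 (SE 0.06) and HXT4 by 0.17 (SE 0.07), and after quantile normalization by 0.14, 0.07 and 0.06. Besides targets, the calcineurin list holds subunit genes of this calcium-activated phosphatase, its transcription factor gene CRZ1 and calcium channel genes. The list, called calcineurin targets below, had a mean of 0.15 (SE 0.10) with 17 of 19 members higher (adjusted p = 0.0108, or adjusted p = 0.831 with an estimated correlation). Among them PUN1 differed by 0.29 (SE 0.09), the vacuolar calcium exchanger gene VCX1 by 0.25 (SE 0.09) and the calcineurin subunit gene CNB1 by 0.14 (SE 0.06). The zinc regulon had a mean of 0.20 (SE 0.22) with 12 of 13 members higher (adjusted p = 0.0281; adjusted p = 0.831 with an estimated correlation). Its members IZH2, IZH1 and ZRT1, the last a zinc transporter gene, differed by 0.39 (SE 0.16), 0.34 (SE 0.12) and 0.17 (SE 0.08), and after quantile normalization by 0.34, 0.26 and 0.02.

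Phospholipid and fatty acid synthesis had a mean of 0.09 (SE 0.04) with 18 of 20 members higher (adjusted p = 0.0107; adjusted p = 0.740 with an estimated correlation). OLE1, a fatty acid desaturase gene, differed by 0.24 (SE 0.08), OPI3 by 0.20 (SE 0.06) and PIS1 by 0.19 (SE 0.06), and after quantile normalization by 0.12, 0.09 and 0.10. The ribosomal protein list was drawn by symbol and also holds RPP1, which is not a ribosomal protein gene. It had a mean of 0.08 (SE 0.08) with 117 of 128 members higher (adjusted p = 7.52e-06, or adjusted p = 0.882 with an estimated correlation). The mean was -0.04 after quantile normalization, where the list passed as lower (adjusted p = 0.00363). RPP0 differed by 0.19 (SE 0.06), RPL30 by 0.17 (SE 0.06), and RPL1B, read from a shared probe set, by 0.16 (SE 0.06), and after quantile normalization by 0.03, 0.01 and -0.01.

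On the lower side, ribosome biogenesis had a mean of -0.14 (SE 0.20) with 49 of 52 members lower (adjusted p = 1.13e-06; adjusted p = 0.831 with an estimated correlation). UTP4 differed by -0.27 (SE 0.16), ERB1 by -0.24 (SE 0.15) and UTP20 by -0.23 (SE 0.13). The list of cytosolic heat shock proteins also holds HSP60, HSP10, HSP78, SSC1 and MDJ1, whose products act in mitochondria. Its mean was -0.09 (SE 0.05) with 24 of 27 members lower (adjusted p = 0.000126, or adjusted p = 0.215 with an estimated correlation). BTN2 differed by -0.36 (SE 0.08), and the co-chaperone genes FES1 and CPR6 by -0.14 (SE 0.05) and -0.13 (SE 0.05). The pheromone response list had a mean of -0.06 (SE 0.06) with 13 of 20 members lower and 14 of the 20 above the background on at least 4 arrays (adjusted p = 0.0374; adjusted p = 0.740 with an estimated correlation). The transcription factor gene STE12 differed by -0.37 (SE 0.15) and PRM5 by 0.42 (SE 0.20). FUS1, a cell fusion gene, had a lower mean in the Kir2.1 arrays but lay within the background on 6 of 8 arrays. Over the 31 lists, 20 members passed adjusted over the list alone: 11 of glycolysis, 8 of cell wall integrity and 1 of ER-associated degradation.

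**Figure D1:**
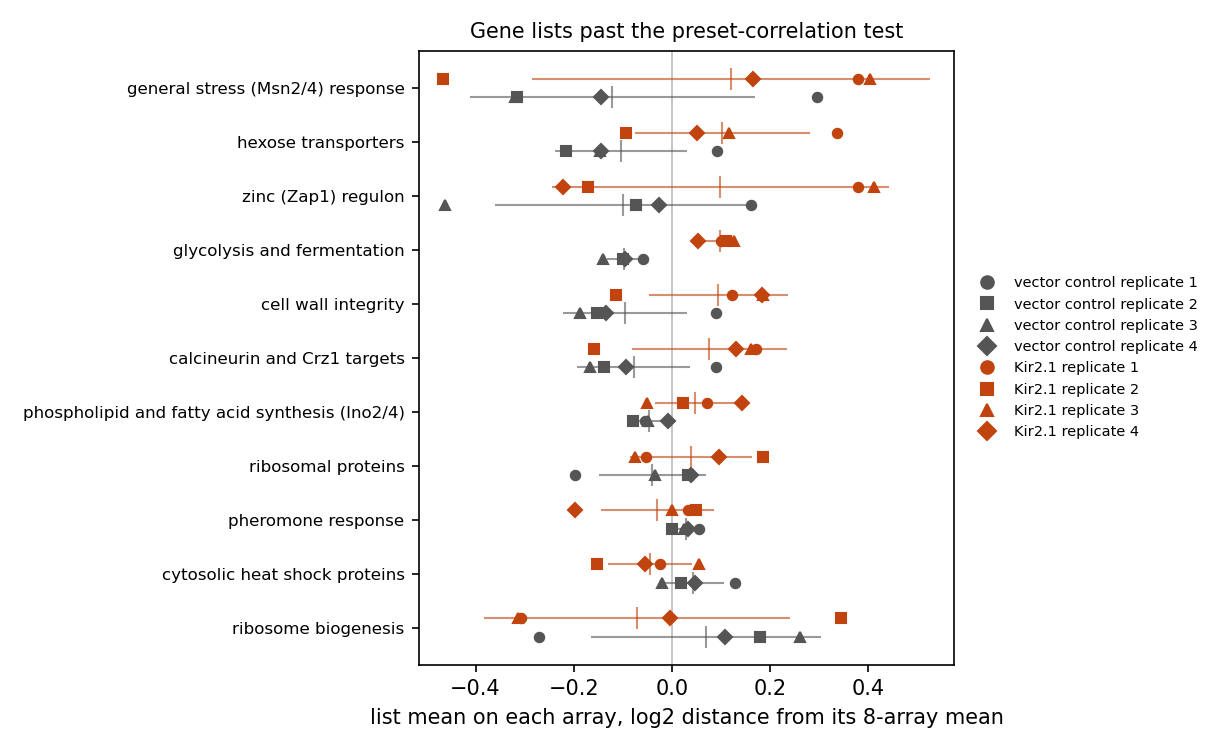
Each row is 1 of the 11 gene lists that passed with the preset correlation, and the horizontal axis gives the mean of the list on each array as a log2 distance from its mean over the 8 arrays. Symbols are arrays (grey, vector control; orange, Kir2.1; shape, replicate number), and vertical ticks and horizontal lines are group means and SD (n = 4). Glycolysis separates the groups, while for general stress vector control replicate 1 stands at 0.30 and Kir2.1 replicate 2 at -0.47.

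Of these 11 calls, 7 missed the threshold when some single array was left out, which also leaves fewer arrays to test. Leaving out Kir2.1 replicate 1 ended the calls of general stress (adjusted p = 0.0798), calcineurin targets (0.0556), hexose transporters (0.0556) and the zinc regulon (0.151). Leaving out Kir2.1 replicate 3 ended general stress (0.220), calcineurin targets (0.0637) and zinc (0.295). Without Kir2.1 replicate 2 the ribosomal proteins (0.389) and phospholipid synthesis (0.0664) were no longer called, and without Kir2.1 replicate 4 the pheromone response (0.423), calcineurin targets (0.0631) and phospholipid synthesis (0.112). Among the controls, omission of replicate 1 ended the ribosomal protein (0.291) and pheromone (0.126) calls, of replicate 2 general stress (0.0509), and of replicate 3 pheromone (0.0526) and zinc (0.290). Over the single omissions the list mean ran from 0.15 to 0.44 for general stress, 0.12 to 0.23 for calcineurin targets, 0.13 to 0.27 for hexose transporters, 0.08 to 0.31 for zinc, 0.06 to 0.13 for phospholipid synthesis, 0.03 to 0.12 for ribosomal proteins and -0.08 to -0.0018 for the pheromone response. Glycolysis, cell wall integrity, heat shock proteins and ribosome biogenesis passed in all 8 single omissions, with means from 0.18 to 0.21, 0.16 to 0.26, -0.12 to -0.05 and -0.28 to -0.06.

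Some calls were also lost without the 3 arrays with high iron regulon values, vector control replicate 1 and Kir2.1 replicates 1 and 3, a test on 5 arrays. There general stress had a mean of 0.11 (adjusted p = 0.411), hexose transporters of 0.15 (0.0892), calcineurin targets of 0.12 (0.0892), the zinc regulon of -0.01 (0.891) and ribosome biogenesis of -0.01 (0.411). The same 5 lists lost their calls with the first principal component as a covariate, at means of 0.06 (0.787), 0.13 (0.164), 0.09 (0.168), 0.04 (0.403) and 0.01 (0.691). Cell wall integrity stayed called in both settings (7.71e-06 and 0.000165) and missed the threshold with both components, where its mean fell to 0.07 (0.0666). Heat shock proteins lost their call without vector control replicate 1 and Kir2.1 replicate 2, where their mean fell to -0.02 (0.136). Quantile normalization also ended the zinc (mean 0.13, adjusted p = 0.0685) and phospholipid (0.03, 0.339) calls and that of the pheromone response, whose mean was larger there (-0.09, 0.111). It gave means of 0.19 for general stress, 0.15 for hexose transporters, -0.15 for heat shock proteins and -0.17 for ribosome biogenesis. The pheromone call was also lost under both dim filters (-0.04 each, 0.0717 and 0.649).

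Protein quality control in the endoplasmic reticulum, where membrane proteins are folded, did not pass. The unfolded protein response list had a mean of 0.02 (SE 0.05, adjusted p = 0.946), with 10 of 19 members higher. JEM1, a chaperone gene of that compartment, differed by -0.21 (SE 0.07). It lay within the background on 1 Kir2.1 array, so its fall may be larger than shown. ER-associated degradation had a mean of 0.02 (SE 0.04, adjusted p = 0.885), although camera, which compares the list with other genes, placed it on the lower side. Its member DSK2, a ubiquitin-binding shuttle gene, differed by 0.31 (SE 0.06) and was the 1 member that passed adjusted over the list alone. After quantile normalization both means were close to 0 (-0.01 and -0.0012), over the single omissions they ran from -0.01 to 0.05 and -0.0049 to 0.04, and neither list passed in any of 31 alternatives. Translocation and N-glycosylation had a mean of 0.05 (SE 0.02, adjusted p = 0.0792), which was -0.01 after quantile normalization, and passed as higher in 1 of 31 alternatives and as lower in 1. STT3, of the oligosaccharyltransferase, differed by -0.27 (SE 0.07). The proteasome had a mean of 0.05 (SE 0.03, adjusted p = 0.0670; 0.0054 and 0.857 after quantile normalization), with PRE9 at 0.14 (SE 0.06; 0.09 after quantile normalization), and passed as higher in 5 of 31 alternatives and as lower in 1. The ESCRT list, for sorting of membrane proteins to the vacuole, had a mean of 0.03 (SE 0.04, adjusted p = 0.946; 0.01 to 0.06 over the single omissions), with SNF8 at 0.29 (SE 0.08). Vacuolar hydrolases and autophagy had a mean of 0.13 (SE 0.18, adjusted p = 0.0822; 0.03 to 0.24 over the single omissions and 0.08 after quantile normalization), with APE3 at 0.19 (SE 0.08; 0.07 after quantile normalization), and passed as higher in 9 of 31 alternatives, among them centring on the 75th percentile (0.0391), the replicate block (0.0397) and 2 of the 8 single omissions.

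The yeast genes for potassium, sodium and proton transport, the ions a potassium channel bears on most directly, did not pass as a list (mean 0.10, SE 0.06, adjusted p = 0.0645, 20 of 25 members higher). Besides transporter genes, the list holds regulator genes such as HAL5, SAT4, PPZ1 and PPZ2. The list passed as higher in 8 of 31 alternatives, among them quantile normalization (mean 0.07, adjusted p = 0.0492), centring on the 75th percentile (0.0463) and 2 of the 8 single omissions. TRK1, the main potassium importer, differed by -0.01 (95% interval -0.19 to 0.17). Its paralog TRK2 differed by 0.09 (-0.13 to 0.30) and the outward channel gene TOK1 by 0.10 (-0.14 to 0.34). PMA1, the proton pump of the plasma membrane, differed by 0.16 (-0.0025 to 0.32), and by 0.03 after quantile normalization. PMP3, a small membrane protein gene, had the smallest p of the list and differed by 0.21 (SE 0.06, adjusted p = 0.551), and by 0.08 after quantile normalization. ENA1, a sodium pump gene, was not analysed here.

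The remaining lists did not pass either. For the responses to osmotic stress, oxidative stress and phosphate starvation the means were 0.10 (SE 0.11, adjusted p = 0.626), 0.09 (SE 0.04, adjusted p = 0.116) and 0.06 (SE 0.14, adjusted p = 0.946), and after quantile normalization 0.06, 0.03 and 0.03. Over the single omissions they ran from 0.04 to 0.17, 0.07 to 0.12 and -0.06 to 0.13. Their leading members were GPD1 at 0.22 (SE 0.10; 0.12 after quantile normalization), VTC1 at 0.20 (SE 0.09; 0.10) and, for oxidative stress, SRX1, which lay within the background on all 8 arrays. Nitrogen catabolite repressed genes had a mean of 0.08 (SE 0.09, adjusted p = 0.516; 0.05 after quantile normalization and 0.03 to 0.14 over the single omissions), with the ammonium transporter gene MEP2 at 0.20 (SE 0.06; 0.09 after quantile normalization). Amino acid biosynthesis had a mean of 0.07 (SE 0.04, adjusted p = 0.181), methionine and sulfur assimilation 0.03 (SE 0.13, adjusted p = 0.458) and ergosterol biosynthesis 0.06 (SE 0.02, adjusted p = 0.0706), and all 3 were negative after quantile normalization (-0.01, -0.03 and -0.01). Over the single omissions they ran from 0.04 to 0.10, -0.04 to 0.12 and 0.04 to 0.07. They passed as higher in 5, 4 and 4 of 31 alternatives, the second as lower in 1. GCN4, SAM1 and ERG10 led them at 0.19 (SE 0.05), 0.16 (SE 0.05) and 0.14 (SE 0.05), and at 0.07, 0.06 and 0.05 after quantile normalization. Pyrimidine genes had a mean of 0.01 (SE 0.13, adjusted p = 0.946), a median of -0.02 and a test on the lower side, with URA8 at 0.14 (SE 0.06), and their mean was -0.04 after quantile normalization and -0.08 to 0.07 over the single omissions. They passed as lower in 2 of 31 alternatives and as higher in 2. The citric acid cycle and respiratory chain had a mean of -0.02 (SE 0.14, adjusted p = 0.893; -0.11 to 0.05 over the single omissions), with the citrate synthase gene CIT1 at 0.22 (SE 0.06; 0.13 after quantile normalization), and passed as lower in 3 of 31 alternatives, quantile normalization among them (mean -0.10, adjusted p = 0.0492), and as higher in 2. The a-specific and alpha-specific mating genes had means of 0.11 (SE 0.10, adjusted p = 0.173) and -0.09 (SE 0.21, adjusted p = 0.893), with MFA1 at 0.29 (SE 0.10) and MF(ALPHA)1 at 0.11 (SE 0.06), the latter -0.02 after quantile normalization. The list means were 0.03 and -0.17 after it, and 0.04 to 0.18 and -0.24 to 0.03 over the single omissions. Of the 7 a-specific genes only 1 lay above the background on at least 4 arrays, so that list could not be tested under the 2 dim filters and its mean is mostly of genes near background. It passed as higher in 2 of the 29 other alternatives. Histones and S-phase genes had a mean of -0.03 (SE 0.05, adjusted p = 0.850; -0.08 after quantile normalization and -0.07 to 0.01 over the single omissions), with HTA1 at 0.20 (SE 0.05; 0.07 after quantile normalization), and passed as lower in 1 of 31 alternatives.

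The widest differences among the lists lay within the groups, in the iron regulon. These genes, under the iron-sensing transcription factor Aft1, take up iron and adapt metabolism to its shortage. The mean of the 26 genes stood 0.99 above its 8-array mean on vector control replicate 1 and 1.26 and 1.35 above it on Kir2.1 replicates 1 and 3. It stood at -0.52, -0.87 and -0.60 on vector control replicates 2, 3 and 4 and at -0.69 and -0.93 on Kir2.1 replicates 2 and 4. FIT2, a cell wall protein gene for siderophore-iron retention, was at 3.95 on vector control replicate 1 and at 4.34 and 4.37 on Kir2.1 replicates 1 and 3, and between -0.67 and 0.01 on the other 5 arrays. The siderophore transporter genes ARN2, SIT1 and ARN1, the mRNA-decay factor gene TIS11 and the reductase gene FRE2 were high on the same 3 arrays, with ranges over the 8 arrays of 4.96, 4.46, 4.33, 4.91 and 3.85. SIT1, TIS11 and FRE2 lay within the background on 1, 3 and 5 arrays, so their ranges are lower bounds. CYC1 had the opposite pattern, at 2.09, 0.81 and 0.61 on these 3 arrays and between 3.27 and 3.43 on the others. Between the labelled groups the iron list differed by 0.49 (SE 0.74, adjusted p = 0.0645; adjusted p = 0.897 with an estimated correlation), and by 0.13 to 0.91 over the single omissions. LSO1, the member with the smallest p, lay within the background on all 8 arrays. The list passed as higher after quantile normalization (mean 0.46, adjusted p = 0.00456) and in 9 further alternatives, and as lower without the 3 high arrays (mean -0.15, adjusted p = 0.0204).

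**Figure D2:**
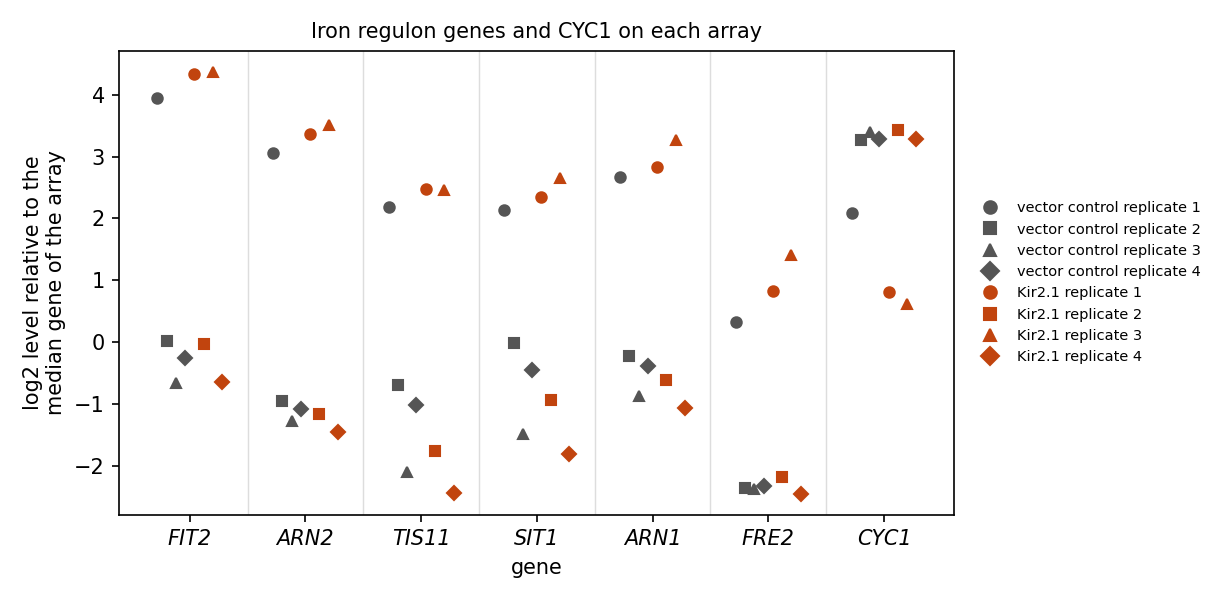
The vertical axis gives the log2 level relative to the median gene of the array, and each symbol is 1 array (grey, vector control; orange, Kir2.1; shape, replicate number) for 6 iron regulon genes and CYC1. Vector control replicate 1 and Kir2.1 replicates 1 and 3 stand apart from the other 5 arrays for each gene, as for FIT2 with values from 3.95 to 4.37 against -0.67 to 0.01.

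The same arrays stood together over all genes. The first principal component held 67.0% of the variance between arrays and set vector control replicate 1 and Kir2.1 replicates 1 and 3 against the others, and Kir2.1 replicate 4 stood apart on the second, which held 18.4%. Vector control replicate 1 and Kir2.1 replicate 3 correlated best with each other. Kir2.1 replicate 2 correlated best with vector control replicate 3, and Kir2.1 replicate 4 with vector control replicate 4. With the first component as a covariate limma called 0 genes, with 930 at an unadjusted p under 0.05, and with both components it called 1 gene, the heat shock gene SSA4, named after this result was seen, which was lower by the fitted difference of -0.50 (SE 0.05, adjusted p = 0.0392).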

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

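The tests of explanations in this part were chosen after the patterns had been seen. In 194 sets of 4 values (list means and named genes, by group), 13 had 1 array far from the other 3, where chance gives about 10. Of the 13, 7 concern vector control replicate 1 and 4 concern Kir2.1 replicate 2, but 3 of the 7 (FIT2, ARN2 and FRE2) are among 6 iron genes picked for their wide range. Without those 6 genes, 10 of 182 sets remain, where chance gives about 9, with 4 on vector control replicate 1. On vector control replicate 1, FIT2 lay 4.26 above the mean of the other 3 controls, ARN2 4.16 and FRE2 at least 2.68 above it, since FRE2 lay within the background on 5 of the 8 arrays. CYC1 stood at a distance of -1.23, UTP4 of -0.40, the pyrimidine list of -0.33 and the alpha-specific mating list of -0.48. On Kir2.1 replicate 2, the calcineurin list stood at -0.31 from the other 3 Kir2.1 arrays, HOR7 at 0.0568, RPL1B at 0.12 and STE12 at 0.59. The remaining arrays set apart were vector control replicate 3 for HOR7 (-0.10) and Kir2.1 replicate 3 for BGL2 (0.0539).

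The iron regulon was high on vector control replicate 1 and Kir2.1 replicates 1 and 3. Kir2.1 expression as labelled is argued against as its cause, because 0 of the 26 genes separated the labelled groups and 3 arrays were out of place. An array-wide difference in scale or background is also argued against, because the list mean ranged over 2.28 on the log2 scale and the widest of 10000 random lists of the same brightness over 0.67. Exchanged labels of vector control replicate 1 and Kir2.1 replicate 2 would separate 2 of the 26 genes, but 1 array alone, Kir2.1 replicate 4, stands in the way, so that explanation cannot be told apart from others for these genes. The iron supply of the cultures may have differed, and no biological explanation of that kind was tested because the labels give no such group.

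The second pattern is 1 of the 35 divisions of the arrays into 4 and 4. The division that exchanges vector control replicate 1 and Kir2.1 replicate 2 called 1445 genes, whereas the other 34, the labelled one included, called 0, which points to a structure of the samples that the labels do not follow. Exchanged labels of these arrays could give this, but the count itself is the pattern and does not test it. The plasmid marker URA3 separated 0 of the 2 divisions, as labelled and exchanged. It would mark an exchange only if the 2 plasmids gave it different levels, which the labels do not say. Exchanged labels therefore cannot be told apart from other explanations. A growth or stress state of the cultures that is not tied to the labels could give the 1445 calls too. The general stress and ribosome biogenesis lists lay on opposite sides of their means on all 8 arrays, which exchanged labels would also allow. The general stress list separated 1 of the 2 divisions, the exchanged one, which exchanged labels would also give. The 2 explanations cannot be told apart, since no probe set for Kir2.1 was analysed here. The labels were kept as deposited throughout.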

How the results depend on the processing

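No centring, other zeros, scores with no log, principal components, the omission of 2 or 3 arrays and the exact permutation test of list means were chosen after seeing the data. Of 29 alternatives that refitted the genes, 26 called 0 genes. Array weights called 1017 higher, 718 lower, 54 at least 2-fold and 2 plasmid-related genes, with 6 lists lower. Leaving out vector control replicate 1 and Kir2.1 replicate 2 called 326 higher, 182 lower and 15 at least 2-fold, and 484 genes were shared with array weights, all in the same direction. These arrays were picked for lying near the other group, so their omission widens the gap by construction, and the array weights are low for them too. Both principal components as covariates gave 1 lower gene. The cause was not tested. Single omissions left 0 genes called, with 211 to 1083 at an unadjusted p under 0.05: 216 and 211 without vector control replicates 2 and 3, 247 without Kir2.1 replicate 1 and 1083 without Kir2.1 replicate 2. They gave 5 to 11 lists higher (5 without Kir2.1 replicate 1) and 2 to 3 lower.

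The list counts of 8 higher and 3 lower became 0 and 0 with an estimated correlation and 1 and 0 with fry. The estimated correlation also passed 0 lists in the exchanged division that called 1445 genes, so its counts say little of stability. The exact permutation test also gave 0 and 0, which says nothing of stability, because 18 lists would have to reach its smallest p for any to pass. Scores with no log gave 5 lists lower. Other scalings moved the split to 6 and 4 (quantile), 11 and 2 (75th percentile) and 11 and 2 (no centring). Quantile normalization changed the sign of 8 of the 31 list means. The other 2 shift every gene by -0.04 and -0.13, so the 5 and 18 signs they change follow from that shift.

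For lists called in the planned test or in the alternative, these values had the other direction. Ribosomal proteins went to -0.0429 with quantile normalization, -0.0414 with array weights, -0.0232 without the 2 arrays and -0.11 score units with no log. With array weights methionine assimilation went to -0.18. With no log, in score units that do not compare in size with log2 values, translocation and N-glycosylation went to -0.0428 and the proteasome to -0.0515, and the pheromone list kept a mean below 0 (-0.00199) but was placed on the higher side and not called. Ribosomal proteins were not called with no log or without the 2 arrays. With the first component as a covariate the pyrimidine list turned to the higher side (0.11) and the citric acid cycle list to 0.0779. With both components, general stress went to -0.0649, pyrimidine to 0.16 and ribosome biogenesis to 0.0713. Without the 3 arrays with high iron values, the iron list went to -0.15 and the citric acid cycle to 0.15. The cause was not tested.

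The replicate numbers do not pair the arrays: within-group deviations of arrays with the same number correlated at 0.81, 0.69, -0.66 and 0.39, and only replicate 1 correlated best with its own number. With the replicate block, 0 genes passed, with 525 at an unadjusted p under 0.05, and 10 lists were higher and 3 lower. The planned floor at a log2 of 4 was not run, because the deposited scale has no such level. Plain scores keep no measure of signal over background beyond the S. pombe probe sets, which limits what can be said of dim genes.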

Other observations

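The tests in this part were chosen after the results had been seen. A set of 3 genes tied to iron use, picked here because their values ran opposite to the iron regulon, had these levels. ACO1, the aconitase gene, stood at 2.48 on vector control replicate 1 and at 2.13 and 2.004 on Kir2.1 replicates 1 and 3, and between 3.01 and 3.28 on the other 5 arrays. LEU1, an isomerase of leucine synthesis with an iron-sulfur cluster, stood at 2.02, 1.86 and 1.69 on these 3 arrays and between 2.56 and 2.95 on the others. GRX4, a glutaredoxin gene that acts in iron sensing, stood at -0.02, -0.10 and -0.23 on them and between 1.20 and 1.53 on the others.

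Of the 5217 probe sets outside the tested genes, limma called 0 between the groups, with 816 at an unadjusted p under 0.05, where 261 would be expected by chance, and of these 814 were higher and 2 lower in the Kir2.1 arrays. Among them were 275 S. pombe probe sets, where 87 would be expected. Levels are relative to the median of the tested genes, so these counts take in any shift of that median against the background. Before centring, that median lay 0.13 lower in the Kir2.1 arrays. Relative to it, the S. pombe median lay from -4.38 to -4.28 on the control arrays and from -4.30 to -4.14 on the Kir2.1 arrays. The probe set of the S. pombe gene cam1 followed the iron genes, at -0.25 on vector control replicate 1, 0.55 and 0.52 on Kir2.1 replicates 1 and 3 and between -3.32 and -2.96 on the others. That of tlg1 did too, at -0.18, 0.42 and 0.46 on these 3 arrays and between -2.96 and -2.68 on the others. S. pombe lsb6 and some probe sets with no annotation entry were also high on the 3 arrays. Some of the S. pombe probe sets used as background thus carried signal that followed the samples.

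Relative to the median gene, bright genes had slightly higher means in the Kir2.1 arrays. This raises the question of whether glycolysis differed for a reason of its own. An intensity-dependent scale difference may account for part of it: 10000 random lists matched on level had a median difference of 0.123, against 0.20 (SE 0.02) for glycolysis. The list mean fell to 0.0411 after quantile normalization, as such a difference would give, but that step gives every array the same highest values and would lower it whatever its source. The list lay at percentile 100 of the random lists, and at 99.05 after quantile normalization. Those lists were drawn gene by gene, whereas the glycolysis genes move together (estimated correlation 0.45). The percentiles therefore cannot decide whether a remainder belongs to glycolysis itself. Matching used 20 bins of level, and glycolysis genes such as PDC1 and ADH1 are among the brightest, so the match is coarse there. A scale difference and a change of glycolysis itself both stay open as hypotheses. A difference in handling was not tested and cannot be told apart from the groups, since only the control arrays are marked as a re-analysis.

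The division of the 8 arrays into 4 and 4 can be made in 35 ways. Since the labelled division called 0 genes, 35 of 35 reach its count by construction, which tests nothing (highest other 1445). For the other 2 counts chance could not be excluded. As many genes with an unadjusted p under 0.05 as the 455 observed came from 6 divisions (highest other 2197). As many lists as the 11 called came from 22 divisions (highest other 19). A structure of the arrays that does not follow the labels, as in the division with 1445 genes, could raise counts in either direction.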
